A study of Mus musculus with 18 samples.

How the data were processed

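Poly(A) RNA purified from total RNA of mouse primary preadipocytes was sequenced by the authors in 18 libraries. Their processing notes name fastp, STAR, featureCounts and genome build mm10; the versions of these tools, the strandedness and the way reads were divided between transcripts are not given in the sources used here. The deposited tables hold estimated counts (expected counts) per RefSeq transcript that were not scaled to a common library size. The table of undifferentiated cells had 32709 transcripts of 17001 gene symbols in 12 libraries, and the table of differentiated cells had 29641 transcripts of 15482 symbols in 6 libraries. Within 0.01, 28.8% and 26% of the transcript values were whole numbers, as were 77% and 73.4% of their sums per gene symbol. No transcript of the differentiated table summed to under 10 over its libraries, while 919 did in the other table. The rule by which low transcripts had been left out is not stated, nor whether it was the same for both. Neither table held a mitochondrial transcript. In each of them, 10 symbols lay on several chromosomes or spanned more than 3 Mb, and their transcripts were summed like the others.

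Columns were assigned to samples by the column names that the labels give. Transcript values were summed per gene symbol and rounded to whole counts with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Depth limited the precision of single genes through sampling noise, and it ranged from 11154449 counts in a CD mock library to 17288608 in an Itga5-Low library. The largest share of 1 gene was that of Col1a1 in all groups except TGF-b1 with SB431542. Groups followed the treatment, diet and sorting labels, with 3 replicates in each of 6 groups. The test, the lists, the rule for named genes and all alternatives except those named below as added were fixed before the data were examined.

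Models were fitted in R 4.3.3 with edgeR 4.0.16. The 12 libraries of undifferentiated cells were fitted together with 1 coefficient per group, and the 6 libraries of differentiated cells separately. Genes were kept by filterByExpr at its defaults, which left 14078 and 13468 genes, libraries were scaled by TMM, and groups were compared with the quasi-likelihood test (estimateDisp, glmQLFit and glmQLFTest at their defaults). P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold. CPM values use the TMM factors. The replicates were so close that the estimated dispersion was below 1e-04 for 3780 and 1746 genes. Below that value edgeR uses an approximate deviance that is inaccurate at very high counts, so standard errors come from a fit with the dispersion kept at 1e-04 or above, and p-values of single genes at very high counts are not printed.

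A total of 19 gene lists and 6 lists of cell type markers were tested with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The lists covered TGF-b and Smad targets, matrix, collagen processing, proteases, contractile genes, integrins, YAP and TAZ targets, BMP genes, adipogenic factors, mature and thermogenic adipocyte genes, energy and lipid metabolism, inflammation, interferon response and cell cycle, with markers of progenitors, macrophages, endothelium, mesothelium, lymphocytes and pericytes. P-values were adjusted by Benjamini-Hochberg over the lists within a comparison, and a list needed 5 tested members. None of the 9 lymphocyte markers was tested in either fit. List calls not given with a further p held with an estimated correlation, though at larger p. For TGF-b targets in TGF-b1 against mock, for example, camera then gave an adjusted p of 0.00494 in place of 1.36e-08. Ccn2 and Timp1 stand on 2 lists each, as do Pparg and Icam1.

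Genes named in the text were taken by a fixed rule for each comparison. They were a set of check genes, among them Itga5, Pparg, Smad7, Acta2, Col1a1, Adipoq and Ucp1, the 5 called genes with the largest change in each direction among those with at least 10 CPM in the higher group and no overlap between libraries, and the 2 called members of smallest adjusted p of each list. Unnamed gene models were passed over. Not every gene taken by the rule is printed, and other members of the lists entered only through their counts.

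Reversal by SB431542 was counted from the calls of the 12-library fit and set beside 100 simulated sets of counts without a group difference. The TGF-b signature took the 200 called genes of smallest p in each direction from TGF-b1 against TGF-b1 with SB431542. Ranking by p favours genes of high counts, where p-values are least exact. The signature therefore also holds abundant genes of actins, translation factors and ribosomal proteins. It was tested with camera and, for the overlap of all calls, with Fisher's exact test against the genes tested in both comparisons, with 4 overlaps per comparison. Figures were drawn with matplotlib 3.10.9.

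The alternatives fixed beforehand were DESeq2's size factors in the same fit, total counts with no further factor, no filter on low counts, DESeq2 1.42.0, limma voom, a minimum log2 fold change of 1, the replicate number as a block, only the 6 libraries compared, leaving out each replicate, an estimated inter-gene correlation, and signatures of 100 and 500 genes. An assumed coefficient of variation of 0.2 between cultures, list tests with total counts, counts and the signature without the marker genes of other cell types, and the dispersion kept at 1e-04 or above were chosen after seeing the data. The replicate numbers did not pair libraries across groups, so the block stayed an alternative.

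The procedure was tested on simulated counts with 200 changed genes per comparison. For TGF-b1 against mock it called 64% of genes changed 1.2-fold, 81.2% at 1.5-fold, 97.9% at 2-fold and 100% at 4-fold, and 7.69% of its calls were false. For HFD against CD it called 72.9%, 84%, 94% and 98% at the same folds, with 4.97% of calls false. For Itga5-High against Itga5-Low it called 52%, 85.7%, 93.8% and 100%, with 2.98% of calls false. Of 100 random lists, 4, 4 and 3 had an unadjusted camera p under 0.05. The simulated genes were drawn independently, with the spread fitted to the replicates and as many genes raised as lowered. Far fewer genes were changed than the real comparisons called. These shares therefore do not cover errors of scaling, correlation between genes or a wider spread between cultures. The surface protein itself and cell counts were not analysed here, since the deposited tables hold RNA counts alone.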

Results

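The transcriptomes of mouse primary preadipocytes, the fat cell precursors of epididymal white adipose tissue, were measured by sequencing of poly(A) RNA in 18 libraries. The libraries fell into 6 groups of 3 replicates. Cells of mice on a control diet (CD) were left as mock, given the cytokine TGF-b1, or given TGF-b1 together with SB431542, an inhibitor of the TGF-b type I receptor kinase and its close relatives. Cells of mice on a high-fat diet (HFD) formed a mock group of their own. The remaining groups had been sorted for high or low surface integrin alpha 5, the product of Itga5, and were harvested after adipogenic differentiation in culture. Total counts ranged from 11154449 to 13846886 per library in CD mock, 12235295 to 16130948 with TGF-b1, and 11811028 to 12599425 with TGF-b1 and SB431542. They ranged from 12698194 to 14729430 in HFD mock, 12043443 to 16721730 in Itga5-High and 15944190 to 17288608 in Itga5-Low.

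Expression is given in CPM, the count of a gene relative to the scaled total of its library (mean ± SD, n = 3 libraries per group), and log2 fold changes are given ± SE from the model. Replicates differed by little more than sampling noise, with a chi-square over its degrees of freedom between 1.15 and 1.25 in the 18 replicate pairs. The labels do not state whether replicates were separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. List counts adjusted over the list alone equalled the counts over all genes tested unless both are given. Positions refer to genome build mm10 and span the RefSeq transcripts of a gene. Itga5 lies on chromosome 15 from 103344286 to 103366792. Col1a1 lies on chromosome 11 from 94936224 to 94953043. Pparg lies on chromosome 6 from 115360951 to 115490402 and Adipoq on chromosome 16 from 23146536 to 23157969.

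The comparison of TGF-b1 with mock asked how the cytokine changed CD preadipocytes. Itga5 rose 3.46-fold, from 376 ± 6.62 to 1299 ± 5.02 CPM. Acta2, the smooth muscle actin of myofibroblasts, rose 3.10-fold to 5817 ± 92.7 CPM. Pparg, the central transcription factor of adipogenesis, fell from 26.0 ± 1.03 to 13.4 ± 0.89 CPM. Adipoq, which encodes adiponectin, was at 3.99 ± 0.668 CPM in mock and at 0.118 ± 0.138 CPM with TGF-b1, where the 3 libraries together held 5 counts.

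Of the 20 measured TGF-b and Smad target genes, 18 rose, 1 fell and 1 was not called (camera adjusted p = 1.36e-08). Ccn2, a secreted matricellular protein, changed by 1.75 ± 0.0092 log2 and Smad7, the inhibitory Smad, by 0.70 ± 0.033. Contractile and myofibroblast genes rose in 13 of 15, with 1 lower and 1 not called (camera adjusted p = 8.28e-08), among them Tagln at 1.47 ± 0.010 and Tpm1 at 1.24 ± 0.0098. YAP and TAZ target genes rose in 12 of 14, with 1 lower and 1 not called (camera adjusted p = 1.31e-05), including Ccn1 at 1.09 ± 0.012. Collagen processing and crosslinking genes rose in 12 of 17 and fell in 5, or 9 higher and 8 lower with scaling by total counts (camera adjusted p = 0.00852), with the crosslinking enzymes Lox at 1.28 ± 0.0078 and Loxl2 at 1.16 ± 0.012. Extracellular matrix proteins split evenly, with 13 higher and 13 lower of 26. Their median was 0.0161 and their mean -0.144 log2, and camera gave no call (adjusted p = 0.986). With scaling by total counts this list had 12 members higher, 14 lower and a median of -0.132. Among its members, Col1a1 rose 1.65-fold and Thbs1 3.46-fold.

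Mature adipocyte genes fell in 19 of 22, with 2 higher and 1 not called (camera adjusted p = 1.9e-05). Lpl, the lipoprotein lipase, changed by -2.81 ± 0.017 log2 and Cd36, a fatty acid transporter, at -2.10 ± 0.045. Adipogenic transcription factors fell in 12 of 15, with 2 higher and 1 not called (camera adjusted p = 0.0038), including Cebpa at -1.48 ± 0.040 and Cebpb at -0.86 ± 0.025. Preadipocyte and fibroblast progenitor markers fell in 12 of 14 and rose in 2 (camera adjusted p = 0.000113), with Cd34 at -3.29 ± 0.064 and Pdgfra at -1.69 ± 0.022. Cholesterol synthesis genes fell in 17 of 19, with 1 higher and 1 not called, or 2 higher and 17 lower adjusted over the list alone (camera adjusted p = 1.9e-05). Fatty acid synthesis genes fell in 10 of 15, with 2 higher and 3 not called (camera adjusted p = 0.0171, or adjusted p = 0.0611 with an estimated correlation), among them Scd1 at -1.15 ± 0.014. Oxidative phosphorylation genes rose in 24 of 26, with none lower and 2 not called (camera adjusted p = 1.76e-05), but in 15 with 3 lower when scaled by total counts. Atp5b rose by 0.45 ± 0.012 and Cycs by 0.69 ± 0.031. Glycolysis and hypoxia genes rose in 10 of 16, with 4 lower and 2 not called (camera adjusted p = 0.0306, or adjusted p = 0.1 with an estimated correlation).

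Interferon response genes fell in 16 of 19 with TGF-b1 and 3 were not called (camera adjusted p = 1.9e-05), with Oasl2 at -2.53 ± 0.090 log2. Inflammatory cytokines and NF-kB targets fell in 14 of 20, with 5 higher and 1 not called (camera adjusted p = 0.0201, or adjusted p = 0.0611 with an estimated correlation and 0.117 with total counts). Ptgs2, which encodes an inducible prostaglandin synthase, rose 12.1-fold, from 57.3 ± 1.66 to 690 ± 4.8 CPM. Markers of other cell types moved alongside these groups. Mesothelial markers fell in 9 of 10 with 1 not called (camera adjusted p = 7.3e-07), Upk3b from 648.4 ± 9.78 to 52.2 ± 1.3 CPM. Endothelial markers fell in 8 of 9 and rose in 1 (camera adjusted p = 0.000262), Cdh5 from 125.8 ± 4.39 to 21.9 ± 1.33 CPM. Macrophage markers rose in 4, fell in 4 and were not called in 6 of 14, with no camera call (adjusted p = 0.944).

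In the quasi-likelihood test of edgeR, 9517 of 14078 genes differed between TGF-b1 and mock at an adjusted p under 0.05, 4705 higher and 4812 lower with TGF-b1. By at least 1 log2 unit, 505 were higher and 1581 lower. The 5 genes that rose most among well expressed genes were C1qtnf3, Gjb2, Acta1, Cdh6 and Col11a1, with Acta1 up 51.9-fold to 212.7 ± 1.85 CPM. The 5 that fell most were Angptl7, Sfrp2, Hp, Cyp2s1 and Megf6, with Hp, which encodes haptoglobin, down from 200.4 ± 5.77 to 2.89 ± 0.143 CPM. In 69.4% of genes the libraries of the groups did not overlap, against 10% by chance. Of the called genes 49.4% were higher with TGF-b1 but 31.4% when libraries were scaled by total counts, which moved the median change of all genes from -0.0165 to -0.164 log2.

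The comparison of TGF-b1 with and without SB431542 asked which effects of the cytokine needed its receptor kinase. With the inhibitor, Itga5 was 8.36-fold lower, at 155.4 ± 5.05 against 1299 ± 5.02 CPM. Acta2 was 6.61-fold lower. Col1a1 fell from 14769 ± 22.8 to 2067 ± 12.1 CPM, a change of -2.84 ± 0.0065 log2. Pparg rose 6.76-fold to 89.8 ± 2.55 CPM, and Adipoq was at 70.4 ± 2.01 CPM against 0.118 ± 0.138 CPM.

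TGF-b and Smad target genes fell in 19 of 20 with SB431542 and rose in 1 (camera adjusted p = 1.31e-08), Ccn2 at -3.00 ± 0.010 log2. Contractile genes fell in 14 of 15 with 1 not called (camera adjusted p = 1.31e-08), Tagln at -2.74 ± 0.012. YAP and TAZ target genes fell in 13 of 14 and rose in 1 (camera adjusted p = 4.59e-06). Collagen processing genes fell in 13 of 17 and rose in 4 (camera adjusted p = 0.000575), Lox from 8152 ± 30.9 to 305 ± 5.64 CPM. Mature adipocyte genes rose in all 22 (camera adjusted p = 1.31e-08), Lpl by 4.14 ± 0.017 and the fatty acid binding protein gene Fabp4 by 3.84 ± 0.034. Adipogenic transcription factors rose in 13 of 15 and fell in 2 (camera adjusted p = 0.000925), Cebpa by 2.48 ± 0.037. Thermogenic and beige adipocyte genes rose in 12 of 15, with 2 lower and 1 not called (camera adjusted p = 0.0371, or adjusted p = 0.0735 with an estimated correlation and 0.203 with total counts). Of the 25 genes fixed for this list, 10 were not tested in undifferentiated cells. Among them was Ucp1, the uncoupling protein of thermogenic fat, which is absent from the counts of those cells. Slc36a2, an amino acid transporter gene of that list, was at 10.1 ± 0.324 CPM against 0.196 ± 0.112 CPM.

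Interferon response genes rose in all 19 with SB431542 (camera adjusted p = 1.31e-08), Ifit3 from 2.94 ± 0.747 to 91.3 ± 0.999 CPM. Inflammatory cytokines and NF-kB targets rose in 16 of 20 and fell in 4 (camera adjusted p = 0.00588, or adjusted p = 0.0811 with total counts), with the complement gene C3 up 33.6-fold. Progenitor markers rose in 11 of 14, with 2 lower and 1 not called (camera adjusted p = 0.00113), Ly6a from 4.39 ± 0.699 to 299.3 ± 2.97 CPM. The markers of other cell types were higher as well. Endothelial markers rose in 8 of 9 and fell in 1 (camera adjusted p = 0.000619), mesothelial markers rose in 8 of 10 and fell in 2 (camera adjusted p = 0.00458), and macrophage markers rose in 13 of 14 and fell in 1 (camera adjusted p = 0.000245). Cdh5 rose 13.2-fold, Upk3b 15.3-fold and Mrc1 14.3-fold. Oxidative phosphorylation genes fell in 18 of 26, with 4 higher and 4 not called, or 19 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.0211, or adjusted p = 0.138 with an estimated correlation and 0.858 with total counts). This list turned with the scaling: with total counts 15 members were higher and 3 lower, and its median went from -0.159 to 0.0981 log2.

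By edgeR's quasi-likelihood test 11223 of 14078 genes differed between TGF-b1 with SB431542 and TGF-b1 alone at an adjusted p under 0.05, 5835 higher and 5388 lower with the inhibitor. By at least 1 log2 unit, 2542 were higher and 1078 lower. Cfd, Car3, Pnoc, Col6a5 and Adipoq were among the genes that rose from very low levels, with 2, 7, 2, 1 and 5 counts over the TGF-b1 libraries, so their folds and the order of these are not reliable. Car3, a carbonic anhydrase gene of adipocytes, was at 253.9 ± 4.27 against 0.183 ± 0.0167 CPM and Cfd, which encodes adipsin, at 102.4 ± 2.85 against 0.045 ± 0.078 CPM. C1qtnf3, Gjb2, Acta1, Col11a1 and Mfap4 fell strongly, C1qtnf3 to 5 counts and Gjb2 to 1 count over the SB431542 libraries, which leaves the folds of these 2 unreliable, and Acta1 was at 0.889 ± 0.212 against 212.7 ± 1.85 CPM. The libraries did not overlap in 80.2% of genes. Of the called genes 52% were higher with SB431542 but 70% with scaling by total counts, which moved the median of all genes from 0.0375 to 0.295 log2.

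**Figure D1:**
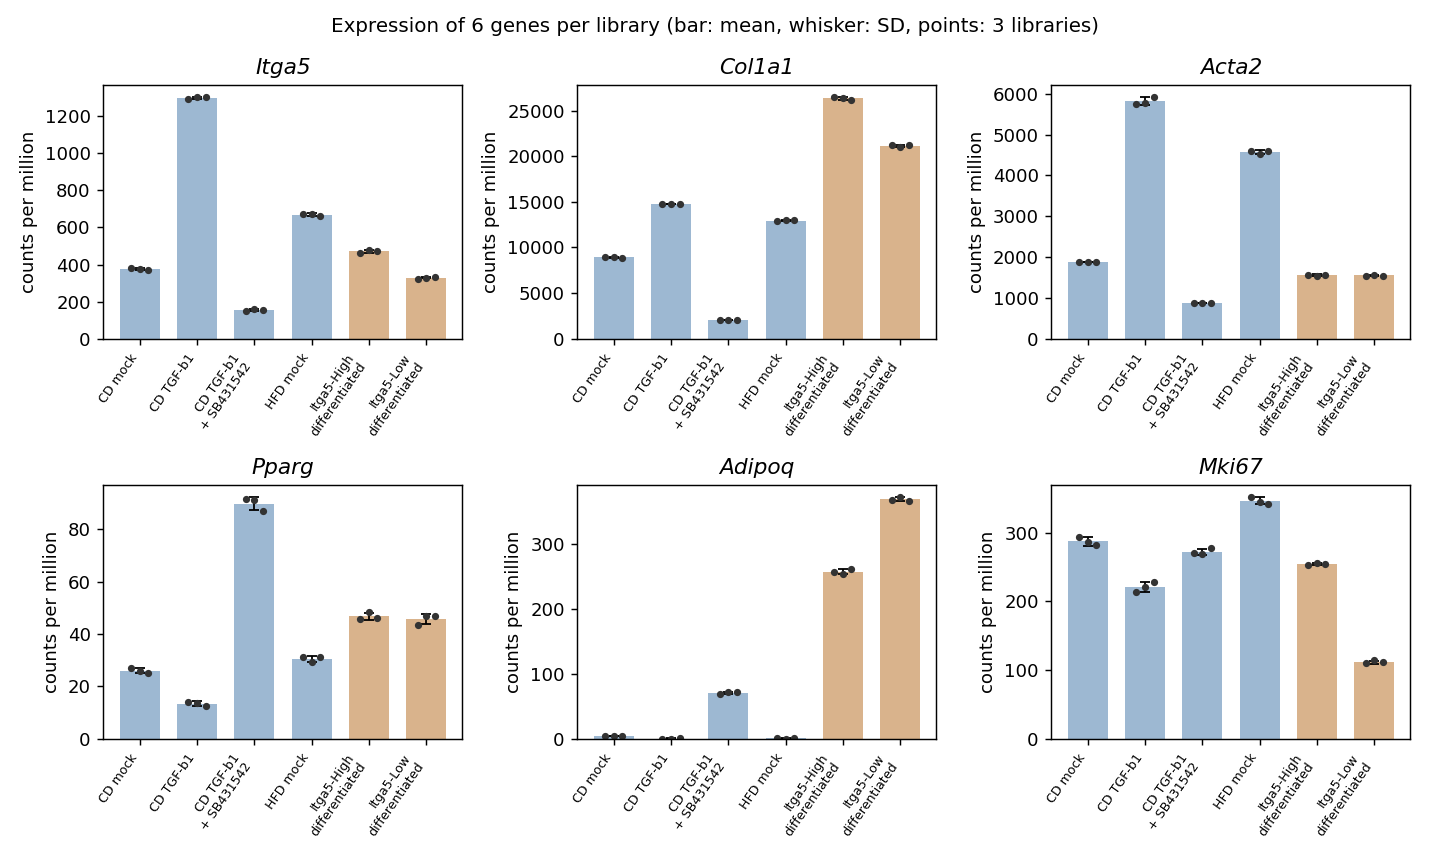
Expression in CPM (vertical axes, linear, from 0) of 6 genes in the 6 groups of libraries (horizontal axes); bars are means, whiskers are SD and points are the 3 libraries, with undifferentiated cells in blue and differentiated cells in tan. Itga5 was at 376 CPM in CD mock, 1299 with TGF-b1, 155.4 with TGF-b1 and SB431542 and 669.9 in HFD mock, while Adipoq reached 256.9 CPM in differentiated Itga5-High and 368.7 in Itga5-Low cells.

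The comparison of TGF-b1 with SB431542 against mock asked how far the inhibitor returned the treated cells to the untreated state. Several TGF-b target genes lay below mock: Itga5 was 2.42-fold lower and Col1a1 4.32-fold lower. Acta2 stood at 880.4 ± 2.1 against 1879 ± 9.4 CPM, a change of -1.09 ± 0.010 log2. Pparg was 3.46-fold higher than in mock and Adipoq 17.7-fold higher, at 70.4 ± 2.01 against 3.99 ± 0.668 CPM.

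TGF-b and Smad target genes were lower than in mock in 16 of 20, with 1 higher and 3 not called (camera adjusted p = 3.99e-08), Pmepa1 at -2.76 ± 0.042 log2. Contractile genes were lower in all 15 (camera adjusted p = 3.75e-11) and YAP and TAZ target genes in 11 of 14, with 1 higher and 2 not called (camera adjusted p = 1.76e-05). Extracellular matrix proteins were lower in 20 of 26 and higher in 6 (camera adjusted p = 3.62e-06), Col1a2 at -1.24 ± 0.0071. Collagen processing genes were lower in 13 of 17 and higher in 4 (camera adjusted p = 1.86e-05), Lox at -3.46 ± 0.011. Cholesterol synthesis genes were lower in 18 of 19 with 1 not called (camera adjusted p = 1.72e-09), Cyp51 at -0.80 ± 0.024 and Hmgcs1 at -0.77 ± 0.023. Fatty acid synthesis genes were lower in 10 of 15, with 4 higher and 1 not called (camera adjusted p = 0.0259 toward lower, or adjusted p = 0.0693 with an estimated correlation). Their median was -0.127 while their mean was 0.434 log2.

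Mature adipocyte genes were higher than in mock in 21 of 22 with 1 not called (camera adjusted p = 3.75e-11), Fabp4 by 2.04 ± 0.022 log2 and Lpl by 1.33 ± 0.011. Adipogenic transcription factors were higher in 12 of 15, with 1 lower and 2 not called, or 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000581). Fatty acid oxidation genes were higher in 15 of 19, with 1 lower and 3 not called (camera adjusted p = 0.00145), though Cpt1a, which controls fatty acid entry into mitochondria, was lower, at -0.73 ± 0.036. Thermogenic and beige adipocyte genes were higher in 9 of 15, with 2 lower and 4 not called (camera adjusted p = 0.0363, or adjusted p = 0.0693 with an estimated correlation, 0.0593 without CD mock replicate 3 and 0.153 with total counts). Oxidative phosphorylation genes were higher in 13 of 26, with 2 lower and 11 not called (camera adjusted p = 0.0331, or adjusted p = 0.149 with an estimated correlation and 0.0569 without CD mock replicate 3), and in 23 with 0 lower with total counts. Interferon response genes were higher in all 19 (camera adjusted p = 1.18e-12), Ifit1 13.4-fold and Ifit3 12.4-fold.

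Beside these groups, macrophage markers were higher than in mock in all 14 (camera adjusted p = 1.67e-09), Lyz2 at 561.4 ± 8.53 against 306.9 ± 2.31 CPM. Endothelial markers were higher in 8 of 9 and lower in 1 (camera adjusted p = 4.94e-05), Pecam1 by 1.46 ± 0.034 log2. Pericyte and smooth muscle markers were higher in 6 of 8, with 1 lower and 1 not called (camera adjusted p = 0.00347). Mesothelial markers were lower in 6 of 10, with 2 higher and 2 not called, or 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0318, or adjusted p = 0.0693 with an estimated correlation). Cell cycle genes were lower in 14 of 23, with 4 higher and 5 not called (camera adjusted p = 0.0318, or adjusted p = 0.0953 with an estimated correlation and 0.106 with total counts). By edgeR's quasi-likelihood test 8587 of 14078 genes differed from mock at an adjusted p under 0.05, 4303 higher and 4284 lower, of which 1102 and 400 by at least 1 log2 unit. Among genes taken by the fixed rule, with at least 10 CPM in the higher group, Car3, Col6a5, Ifit3b, Adipoq and Clec3b rose most. Crabp2, Lama1, Mfap4, Ncam1 and Cilp fell most by the same rule, though Crabp2 had only 9 counts over the SB431542 libraries. Ncam1, a neural cell adhesion molecule gene, was at 3.19 ± 0.216 against 94.8 ± 2.32 CPM. The libraries did not overlap in 64% of genes. Of the called genes 50.1% were higher but 67.7% with scaling by total counts, which moved the median of all genes from 0.0063 to 0.116 log2.

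Gene by gene, 8436 of the 9517 genes called with TGF-b1 against mock (88.6%) were called in the opposite direction when SB431542 was added, and 320 were called in the same direction. In 100 simulated sets with no group difference that shared the TGF-b1 libraries in the same way, edgeR's quasi-likelihood test called 0 genes in opposite directions, and a mean of 132 genes (at most 159) had opposite changes at an unadjusted p under 0.05 in both comparisons. Because these sets hold no true change, they do not show how many of the 8436 calls came from the shared TGF-b1 libraries. Of the 9517 genes, 6599 (69.3%) still differed from mock with the inhibitor present. For 5236 of them (55% of the 9517) the level had passed beyond mock, and for 1363 (14.3%) it stayed on the TGF-b1 side. The shares were not recomputed with scaling by total counts, which moves the medians of both comparisons with mock in opposite directions. Across genes, which are not independent replicates, the covariance of the TGF-b1 and SB431542 fold changes was -0.916 against -0.00975 in the simulated sets. The corresponding r was -0.887 against -0.508.

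The comparison of HFD with CD asked how preadipocytes of mice on a high-fat diet differed from those of controls without added cytokine. Acta2 was 2.44-fold higher in HFD cells, at 4576 ± 49.4 against 1879 ± 9.4 CPM. Itga5 was 1.78-fold higher at 669.9 ± 7.07 CPM and Col1a1 1.45-fold higher. Markers of macrophages were higher too, with Lyz2, which encodes lysozyme, at 1163 ± 3.5 against 306.9 ± 2.31 CPM and the complement gene C1qa 9.73-fold higher. Markers of mesothelium and endothelium were lower, with Upk3b at 157.2 ± 5.05 against 648.4 ± 9.78 CPM. Adipoq was at 0.290 ± 0.178 CPM against 3.99 ± 0.668 CPM.

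Contractile genes were higher in 14 of 15 in HFD cells and lower in 1 (camera adjusted p = 2.68e-11), Tagln by 1.02 ± 0.010 log2 and Myh9 by 0.61 ± 0.0081. TGF-b and Smad target genes were higher in 16 of 20, with 2 lower and 2 not called (camera adjusted p = 2.4e-06), Ccn2 by 1.30 ± 0.0093 and Smad7 by 0.36 ± 0.034. Collagen processing genes were higher in 12 of 17, with 3 lower and 2 not called, or 13 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.000137). YAP and TAZ target genes were higher in 11 of 14, with 2 lower and 1 not called (camera adjusted p = 0.000364), Ankrd1 by 2.07 ± 0.035. Extracellular matrix proteins were higher in 15 of 26, with 10 lower and 1 not called, and were not called as a list (camera adjusted p = 0.0739, or adjusted p = 0.0299 with total counts). In the same libraries the pericyte and smooth muscle markers, a cell type that also expresses contractile genes, were lower in 6 of 8, with 1 higher and 1 not called (camera adjusted p = 0.00208), Rgs5 at -1.01 ± 0.043.

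All 14 macrophage markers were higher in HFD cells (camera adjusted p = 8.77e-15), with a median of 2.47 log2. All 10 mesothelial markers (camera adjusted p = 2.43e-11) and all 9 endothelial markers (camera adjusted p = 4.64e-08) were lower, with medians of -1.91 and -1.82. Cholesterol synthesis genes were lower in 17 of 19, with 1 higher and 1 not called (camera adjusted p = 7.39e-08). Fatty acid synthesis genes were lower in 12 of 15 with 3 not called (camera adjusted p = 2.88e-06), Scd1 at -1.24 ± 0.014 log2. Interferon response genes were lower in 14 of 19 with 5 not called (camera adjusted p = 0.000987), Oasl2 at -1.34 ± 0.065. Mature adipocyte genes were lower in 14 of 22, with 5 higher and 3 not called (camera adjusted p = 0.0192, or adjusted p = 0.0696 with an estimated correlation and 0.0888 with total counts), while Cd36, a gene that macrophages also express, was higher by 0.90 ± 0.026. Adipogenic transcription factors had no camera call (adjusted p = 0.5), with 5 higher, 2 lower and 8 not called, or 5 higher and 1 lower adjusted over the list alone, and turned to 5 higher and 8 lower with total counts. Pparg was at 30.4 ± 1.09 against 26.0 ± 1.03 CPM. Cell cycle genes were higher in 13 of 23, with 1 lower and 9 not called (camera adjusted p = 0.01, or adjusted p = 0.0634 with an estimated correlation and 0.0773 with total counts, which gave 6 higher and 5 lower), with Ccnd1 by 1.13 ± 0.042. Glycolysis and hypoxia genes were higher in 12 of 16, with 3 lower and 1 not called (camera adjusted p = 0.00721, or adjusted p = 0.0634 with an estimated correlation).

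By edgeR's quasi-likelihood test 7566 of 14078 genes differed between HFD and CD at an adjusted p under 0.05, 3821 higher and 3745 lower in HFD, of which 615 and 1037 by at least 1 log2 unit. Among genes taken by the fixed rule, with at least 10 CPM in the higher group, Fat3, Cd72, Spn, Fcgr1 and Slamf9 rose most. All but Fat3 encode surface proteins of blood cells. Cd72 was at 46.9 ± 0.955 against 2.36 ± 0.047 CPM. By the same rule C7, Ppl, Dlk1, Enpp2 and Krt19 fell most, and Dlk1, a preadipocyte marker, was at 5.41 ± 0.592 against 36.6 ± 2.75 CPM. The libraries did not overlap in 58% of genes. Of the called genes 50.5% were higher in HFD but 33.7% with scaling by total counts. The labels do not give the number of mice behind the HFD and CD libraries.

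The HFD and TGF-b1 changes overlapped. Of the genes called higher in HFD, 2085 were also higher with TGF-b1 against mock, where independent lists would share 1277. Of those called lower, 2464 were also lower with TGF-b1, against 1280 for independent lists. The opposite combinations held 828 and 555 genes, against 1306 and 1252. Both comparisons use the same CD mock libraries, and part of the excess may come from these shared controls. The covariance across genes, which are not independent replicates, was 0.248 against 0.00988 in 100 simulated sets without a group difference that shared the controls, whereas r was 0.456 against 0.512. A signature with no library in common with HFD or CD was therefore taken from TGF-b1 against TGF-b1 with SB431542, as the 200 most significant genes in each direction. Of the 200 genes higher with TGF-b1, 154 were higher and 34 lower in HFD (camera adjusted p = 1.05e-20). Of the 200 lower genes, 154 were lower and 38 higher (camera adjusted p = 9.3e-21). These 200 include 4 mesothelial, 3 endothelial and 1 pericyte marker, all lower in HFD, and 1 macrophage marker, which was higher. Without the marker genes of other cell types, a test chosen after seeing the data, 146 were lower and 37 higher of 191. Their median was -0.637 in place of -0.711 log2 (camera adjusted p = 9.7e-20). The fixed marker lists are short, so leaving them out does not remove a difference in cell types from the signature. Across all calls, 2081 genes were higher in both, against 1462 for independent lists (odds ratio 2.51, Fisher's exact test, two-sided, p = 3.29e-126), and 2366 were lower in both, against 1552 (odds ratio 3.39, Fisher's exact test, two-sided, p = 3.4e-216). The opposite combinations held 1225 and 873 genes, against 1584 and 1433. Fisher's test takes genes as independent, which they are not, so its p-values overstate the evidence and do not measure the spread between animals or cultures.

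The comparison of Itga5-High with Itga5-Low cells after differentiation asked how cells sorted by surface integrin alpha 5 differed once adipogenesis had been induced. Itga5 itself was 1.43-fold higher in the High group, at 471.6 ± 8.82 against 329.4 ± 4.68 CPM. Adipoq was lower, at 256.9 ± 3.82 against 368.7 ± 3.14 CPM, and Pparg did not pass the test, at 46.8 ± 1.3 against 45.7 ± 1.86 CPM (edgeR quasi-likelihood adjusted p = 0.597). Mki67, a marker of proliferating cells, was 2.28-fold higher in the High group. Col1a1 was 1.25-fold higher. Ucp1 stood at 4.23 ± 0.189 against 4.86 ± 0.771 CPM and did not pass the test (edgeR quasi-likelihood adjusted p = 0.335).

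Cell cycle genes were higher in Itga5-High cells in all 23 (camera adjusted p = 7.64e-16, or adjusted p = 0.0451 with an estimated correlation), with a median of 1.05 log2 and Top2a at 1.05 ± 0.028. Collagen processing genes were higher in 15 of 17 with 2 not called (camera adjusted p = 3.25e-07, or adjusted p = 0.0451 with an estimated correlation), Loxl2 by 0.75 ± 0.011 and the collagen chaperone Serpinh1 by 0.40 ± 0.0075. Glycolysis and hypoxia genes were higher in 14 of 16, with 1 lower and 1 not called (camera adjusted p = 8.02e-06, or adjusted p = 0.046 with an estimated correlation), Ldha by 0.53 ± 0.0094 and Eno1 by 0.51 ± 0.010. Mature adipocyte genes were lower in 17 of 23, with 3 higher and 3 not called (camera adjusted p = 5.09e-05, or adjusted p = 0.046 with an estimated correlation), Acsl1 at -0.86 ± 0.014 and Lpl at -0.18 ± 0.0078. Fatty acid oxidation genes were lower in 14 of 19, with 2 higher and 3 not called (camera adjusted p = 0.00985, or adjusted p = 0.414 with an estimated correlation). TGF-b and Smad target genes were higher in 12 of 20, with 3 lower and 5 not called, and had no camera call (adjusted p = 0.0632). Extracellular matrix proteins were higher in 13 and lower in 13 of 26, with a median of 0.036, a mean of -0.137 log2, Col3a1 at -0.31 ± 0.0054 and Postn at -0.51 ± 0.0066 (camera adjusted p = 0.973). Acta2 was not called, at 1556 ± 19.8 against 1549 ± 15.3 CPM. With scaling by total counts its log2 fold change went from 0.0073 to -0.0334, which was called lower. Contractile genes were higher in 6 and lower in 8 of 15 with 1 not called (camera adjusted p = 0.956).

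Thermogenic and beige adipocyte genes were higher in 6, lower in 7 and not called in 10 of 23 in this comparison (camera adjusted p = 0.958), with a median of -0.104 and a mean of 0.151 log2. Slc36a2 was lower, at -0.84 ± 0.053, and Tnfrsf9 was at 4.65 ± 0.489 against 0.356 ± 0.148 CPM. Progenitor markers were higher in 5, lower in 6 and not called in 3 of 14 (camera adjusted p = 0.958), with a median of 0.0296 and a mean of -0.281 log2, Cd34 at -1.90 ± 0.075. Of 14 macrophage markers 5 were tested, 3 of them higher and 2 not called (camera adjusted p = 0.236), with Csf1r at 29.5 ± 0.626 against 9.54 ± 0.69 CPM. Of 9 endothelial markers 7 were tested, 1 of them higher, 2 lower and 4 not called, or 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.958), with a median of 0.105 and a mean of -0.047 log2. Only 2 of 10 mesothelial markers were tested, and Krt19 was higher by 1.31 ± 0.041. Pericyte and smooth muscle markers were higher in 2 and lower in 4 of 6 (camera adjusted p = 0.407).

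By edgeR's quasi-likelihood test 7199 of 13468 genes differed between Itga5-High and Itga5-Low at an adjusted p under 0.05, 3635 higher and 3564 lower in the High group, of which 274 and 281 by at least 1 log2 unit. Among genes taken by the fixed rule, with at least 10 CPM in the higher group, Tpsab1, Nos2, H2-Q10, H2ac24 and Car4 rose most. Nos2, which encodes an inducible nitric oxide synthase, was at 18.0 ± 0.948 against 2.73 ± 0.174 CPM. By the same rule C7, Cilp, Scg2, Sema3d and Pi16 fell most, and Cilp, a matrix protein gene, was at 45.4 ± 1.55 against 423.2 ± 6.68 CPM. The libraries did not overlap in 58.2% of genes. The TGF-b signature, which shares no library with these cells, was tested here as well. Of its 200 genes higher with TGF-b1, 115 were higher and 58 lower in Itga5-High (camera adjusted p = 0.000228), with a median of 0.121 log2. Of the 190 measured lower genes, 105 were lower and 56 higher (camera adjusted p = 0.000544), with a median of -0.149. Across all calls 2065 genes were higher in both, against 1427 for independent lists (odds ratio 2.77, Fisher's exact test, two-sided, p = 9.68e-143), and 1887 were lower in both, against 1361 (odds ratio 2.34, Fisher's exact test, two-sided, p = 1.88e-99). The opposite combinations held 941 and 1047 genes, against 1386 and 1401. Genes are not independent here either, so these p-values overstate the evidence. Since the TGF-b target list (camera adjusted p = 0.0632) and the contractile list (camera adjusted p = 0.956) were not called here, the shift of the signature is not shown to be specific to TGF-b. The series holds no libraries of the sorted groups from before differentiation.

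**Figure D2:**
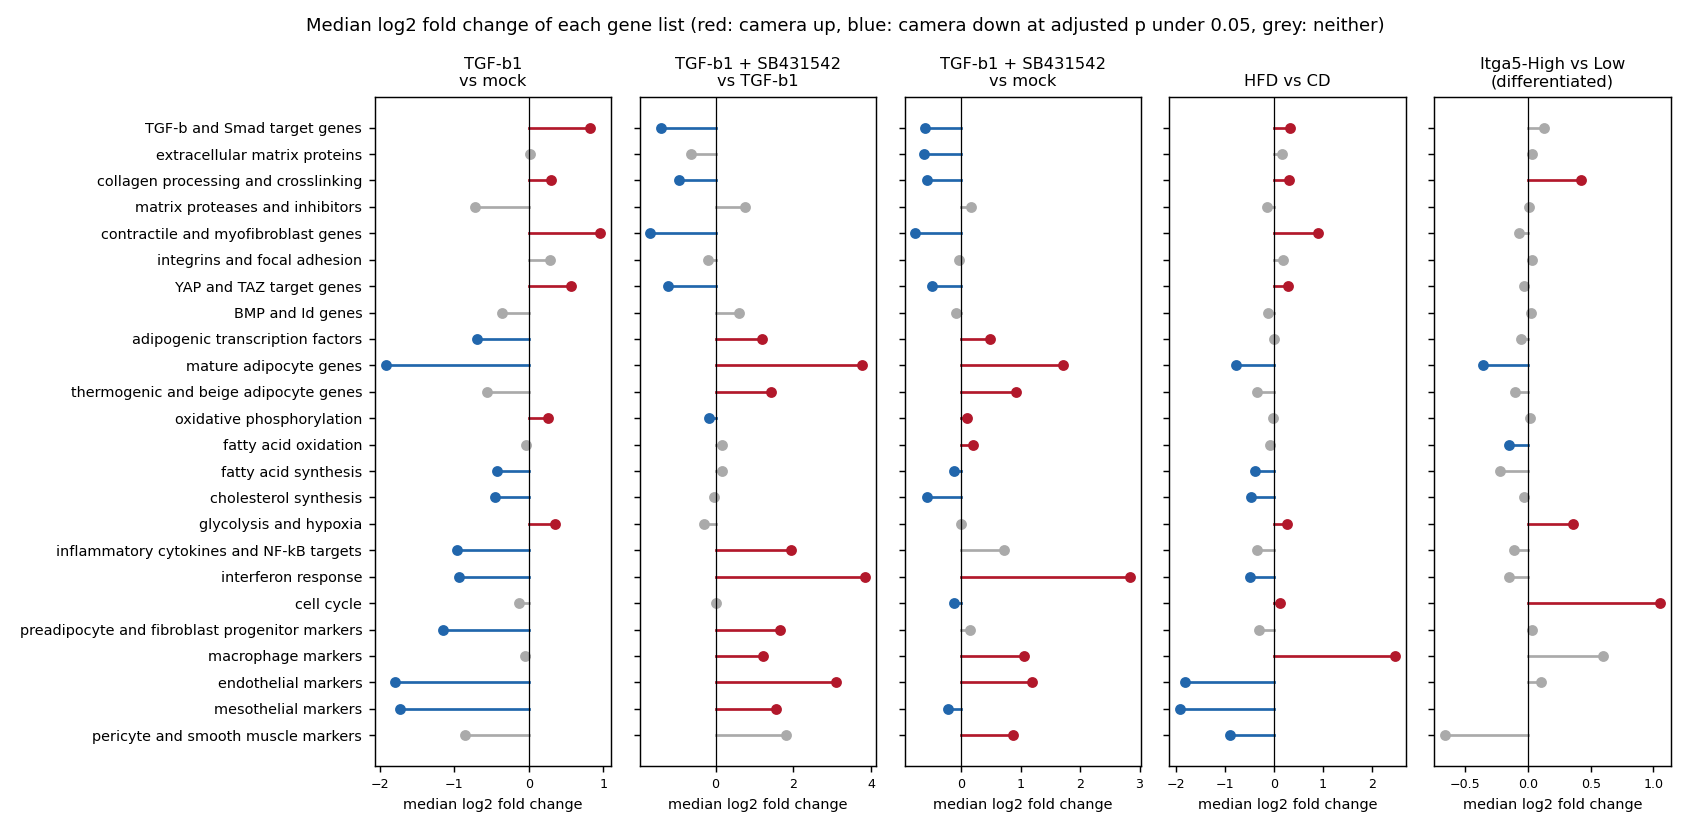
Median log2 fold change of the tested members of each gene list (horizontal axes, 1 panel per comparison with its own scale); red points are lists called higher and blue points lists called lower by camera at an adjusted p under 0.05, and grey points are not called. Contractile genes stood at 0.96 with TGF-b1, -1.67 with SB431542 against TGF-b1, -0.769 against mock, 0.9 in HFD and -0.0724 in Itga5-High; oxidative phosphorylation genes in SB431542 against TGF-b1 change sign with scaling by total counts.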

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

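The alternatives with an assumed coefficient of variation of 0.2, list tests with total counts, counts and the signature without marker genes of other cell types, and the dispersion kept at 1e-04 or above were chosen after seeing the data; the others were planned. The counts of called genes stayed within 1.5 times their values with DESeq2's size factors, DESeq2, limma voom, no filter, the replicate block, the 6 libraries compared, the dispersion kept at 1e-04 or above, and without the marker genes. Leaving out 1 replicate gave 4458 to 4583 genes higher and 4482 to 4631 lower with TGF-b1 against mock, 5625 to 5799 and 5129 to 5358 with SB431542 against TGF-b1, 3951 to 4170 and 3894 to 4129 against mock, 3526 to 3616 and 3472 to 3555 in HFD, and 3312 to 3424 and 3142 to 3327 in Itga5-High.

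With total counts, genes higher with TGF-b1 against mock dropped to 3068, genes lower with SB431542 against TGF-b1 to 3446 and genes lower with SB431542 against mock to 2840, since the scaling itself moves all fold changes of a comparison together. With a minimum log2 fold change of 1, which by construction leaves fewer genes, counts higher and lower were 505 and 1581 for TGF-b1 against mock, 2542 and 1078 for SB431542 against TGF-b1, 1102 and 400 against mock, 615 and 1037 for HFD, and 274 and 281 for Itga5-High. Of the 2086 TGF-b1 genes called under it, 1894 (90.8%) were called opposite with SB431542 and 818 (39.2%) against mock, 741 (35.5%) beyond mock and 77 (3.69%) on the TGF-b1 side, in place of 69.3%, 55% and 14.3% against mock, beyond it and on the TGF-b1 side. With an assumed coefficient of variation of 0.2, which widens the spread by construction, they were 1012 and 2112, 3520 and 2423, 1505 and 723, 868 and 1320, and 432 and 407 in the same order. Of 303 named-gene results 62 lost their call with it, and 113 with the minimum fold change. Several lists lost most of their called genes under the assumed variation: oxidative phosphorylation with TGF-b1 against mock went from 24 to 1 higher, cholesterol synthesis and interferon response in HFD from 17 to 4 and from 14 to 2 lower, and glycolysis and hypoxia in Itga5-High from 14 to 1 higher. In HFD the TGF-b target list went from 16 to 6, YAP and TAZ targets from 11 to 3, collagen processing from 12 to 3 and contractile genes from 14 to 10 higher. In Itga5-High mature adipocyte genes went from 17 to 4 and fatty acid oxidation from 14 to 1 lower, and TGF-b targets from 12 to 0 and collagen processing from 15 to 5 higher.

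Of the named genes, Acta2 in Itga5-High reversed with total counts, from a fold change that was not called to -0.0334 log2, and Atp5b in SB431542 against mock was no longer called there (-0.0048 log2). Both moved by the shift that the scaling gave all genes of the comparison, whose median went from -0.00333 to -0.044 log2 in Itga5-High and from 0.0063 to 0.116 in SB431542 against mock. With an estimated correlation 14 list calls were lost and 105 of the list results kept their direction and side of the threshold. Without TGF-b1 replicate 3, the BMP list (adjusted p = 0.0481) and the integrin list (adjusted p = 0.0476) passed in TGF-b1 against mock, and without SB431542 replicate 2 the fatty acid oxidation list passed against TGF-b1 (adjusted p = 0.0452). In list tests with total counts 8 calls were lost and 5 lists passed that had not, among them cell cycle lower with TGF-b1 against mock (adjusted p = 0.0206), and extracellular matrix (0.0223) and fatty acid oxidation (0.0117) in SB431542 against TGF-b1. The TGF-b signature kept its direction and call in HFD and in Itga5-High with 100 or 500 genes, without the marker genes and without each replicate, but its size varied. The median of the lower genes in Itga5-High went from -0.149 to -0.0783 log2 with 100 genes (adjusted p = 0.035) and -0.0799 with 500, and in HFD from -0.711 to -0.462 with 500. Genes with few counts in a group, such as Cfd with 2 counts over the TGF-b1 libraries, have levels but no reliable fold at this depth.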

Other observations

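The tests of pericyte markers, of the share of fibroblasts in both comparisons and of macrophage markers were chosen after the result was seen; the other tests were set before it was seen. Several groups of genes stood apart from the main changes. Matrix proteases and inhibitors went both ways with TGF-b1 against mock, with 6 higher and 11 lower of 17 (camera adjusted p = 0.0726), as Timp3 rose from 1427 ± 7.2 to 3541 ± 14.4 CPM while Mmp3, a stromelysin gene, fell from 182.3 ± 0.449 to 7.83 ± 1.15 CPM. In HFD against CD both were lower, Timp3 at -1.14 ± 0.013 log2 and Mmp3 at -2.01 ± 0.039. BMP and Id genes were higher in 4, lower in 10 and not called in 1 of 15 with TGF-b1 (camera adjusted p = 0.0565, and adjusted p = 0.0481 without TGF-b1 replicate 3), with Bmp4 at -2.00 ± 0.096. Integrins and focal adhesion genes were higher in 11, lower in 6 and not called in 3 of 20 with TGF-b1 (camera adjusted p = 0.0555, and adjusted p = 0.0476 without TGF-b1 replicate 3 and 0.0177 with total counts). Itga11, a collagen receptor gene, was at 448 ± 4.03 CPM with TGF-b1 and 14.2 ± 0.732 CPM with SB431542 added.

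Ccnd1, which encodes cyclin D1, changed with both treatments. It was at 50.1 ± 2.29 CPM in mock, fell with TGF-b1 (-1.57 ± 0.068 log2) and was at 154.7 ± 3.42 CPM with SB431542 added, while the cell cycle list went both ways in SB431542 against TGF-b1, with 11 higher and 11 lower of 23 (camera adjusted p = 0.962), and turned to 14 higher and 5 lower with total counts. Notch3 and Cspg4, both on the pericyte list, moved apart with TGF-b1 against mock, Notch3 lower at -1.19 ± 0.047 log2 and Cspg4 higher by 2.77 ± 0.050. Of the 8 markers of this list 2 were higher and 6 lower, with a median of -0.85 log2 and no camera call (adjusted p = 0.0871). For each comparison the 6 libraries allow 10 splits into 3 and 3, which cannot give a share under 0.05. The real split (1 of the 10) called 9234 genes for TGF-b1 against mock, 11097 for SB431542 against TGF-b1, 8533 for SB431542 against mock, 7434 for HFD and 7199 for Itga5-High in edgeR fits of the 6 libraries alone. The highest other split called 0 in each, with at most 75, 19, 105, 137 and 134 genes at an unadjusted p under 0.05 in the same order. Each other split mixes libraries of both groups on each side, so the group difference widens its spread. Their low counts follow by construction and do not measure what chance would give.

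Contractile and TGF-b target genes were higher in HFD cells. More pericytes or smooth muscle cells would raise their markers, but the median of these was -0.9 log2. TGF-b1 alone gave this list a similar median of -0.85 log2 in CD cells, with 2 higher and 6 lower (camera adjusted p = 0.0871). The markers may therefore follow the treatment as well as the number of cells, and their fall cannot decide the question. If the TMM scaling made the rise, total counts would remove it, but with them the contractile median was 0.816. That change of scaling moved the median of all genes only from -0.00769 to -0.0911 log2, so a larger error of scaling was not tested. A TGF-b type response of the HFD cells is a candidate explanation: the 200 genes higher with TGF-b1 than with SB431542 added had a median of 0.302 in HFD, called by camera. Of these, 154 were higher and 34 lower in HFD. Not every TGF-b1 change recurred: adipogenic transcription factors fell in 12 of 15 with TGF-b1 but had no camera call in HFD (adjusted p = 0.5). The labels do not state how many mice or cultures stand behind each diet, and other stimuli that raise the same genes were not tested.

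Macrophage markers were higher and mesothelial and endothelial markers lower in HFD cells. A lower share of fibroblasts alone would raise all of them alike, but the medians of the macrophage and mesothelial lists lay 4.38 log2 apart. That gap is the pattern itself, seen before the test was chosen, so it cannot decide whether the share of fibroblasts differed. With TGF-b1 in CD cells the mesothelial and endothelial medians were -1.73 and -1.79 log2, against -1.91 and -1.82 in HFD. The macrophage median was -0.0569 with TGF-b1 and 2.47 in HFD. The mesothelial and endothelial falls alone therefore do not tell fewer such cells from a response like that to TGF-b1. Fibroblast progenitor markers were higher in 5 and lower in 8 of 14 in HFD cells, with 1 not called (camera adjusted p = 0.116). All 14 macrophage markers were higher, none of which stands on another list, with Lyz2, the most abundant of them, at 1163 against 306.9 CPM, and this is consistent with more macrophages in the HFD cultures, although all 14 were also expressed in CD mock. The labels name no sort that would have removed them from these cultures. A change of expression within the cells present stays open.

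With SB431542, TGF-b target and contractile genes were below mock. If the TMM scaling made this, total counts would bring them back to mock, but with them the contractile median stayed at -0.66 log2. That change of scaling moved the median of all genes only from 0.0063 to 0.116 log2, so a larger error of scaling was not tested. Shared mock libraries would give a positive correlation of the TGF-b1 and SB431542 changes, but r across genes was -0.439. A lower share of fibroblasts would raise the markers of other cells alike, and macrophage (median 1.05), endothelial (1.2) and pericyte markers (0.871) did rise by similar amounts, while the mesothelial median of -0.224 (camera adjusted p = 0.0318, or adjusted p = 0.0693 with an estimated correlation) lay 1.42 log2 below the endothelial one. This gap cannot decide the question, since both lists also moved with TGF-b1 itself. The mesothelial median was -1.73 with TGF-b1 against mock and 1.56 with SB431542 against TGF-b1, and the endothelial median -1.79 and 3.09. A lower share of fibroblasts stays open. Fibroblast progenitor markers were at 7 higher, 5 lower and 2 not called of 14 (camera adjusted p = 0.149), or 8 higher and 1 lower with total counts. A candidate explanation is that mock cells respond to TGF-b family ligands already present in the culture, which the inhibitor may block, but no group had the inhibitor alone and this was not tested.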
